A study of Mus musculus with 3 samples.

How the data were processed

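Polyadenylated RNA of CD45-selected cells from infarcted mouse hearts was measured in 3 multiplexed libraries on the BD Rhapsody platform. Per the labels' protocols, hearts were digested enzymatically, dead cells were depleted, CD45-positive cells were selected on microbeads, and the cells of each biological replicate were tagged before pooling. The 18 files each held the cells of 1 sample tag, 7 tags in library 1, 5 in library 2 and 6 in library 3. The deposited values are molecule counts per cell and gene, deduplicated and corrected for sequencing errors in the molecular identifiers by recursive substitution (RSEC), per the file headers. Library 1 was made with pipeline version 2.0b1 on enhanced beads with intronic reads kept in, and libraries 2 and 3 with an earlier release on the original beads, per the file headers. The reference was GRCm38 with GENCODE M19, per the file headers and the submitters' processing notes. The aligner's settings are not given in the sources used here. How reads shared by near-identical copies such as Hspa1a and Hspa1b, or with pseudogenes of Gapdh, Fth1 and Ftl1, were counted is not given there either, so these members of the lists are uncertain. Identifiers and positions of F7 and F10 were looked up by symbol in GENCODE M21 for the same build.

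Neither labels nor headers assign a genotype or a time point to single tags, and the table of tags that the labels mention was not used here. Comparisons between genotypes, times or hearts were therefore left out, values per tag were given singly or as median and range, and tests were made between cells of the same tag only. The libraries differ in beads, pipeline release and intronic reads, and their mix of genotypes and times is not given. The run name of library 1 includes d3, possibly a day of the whole pool, and the names of libraries 2 and 3 hold no day. Library and time may therefore coincide, and differences between libraries are given without a reading. A check of all 46 pairs of files within a library found 0 identical pairs.

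Cells with fewer than 200 genes (122 of 25762) were left out. Doublet scores came from Scrublet in scanpy 1.11.5 per library, with an expected rate of 6%. Its automatic threshold called 0, 1 and 1 cells, so the 2% of cells with the highest scores were left out instead, 512 in all. The remaining 25128 cells were scaled to equal totals and log-transformed, 2000 variable genes were centred and scaled within each library, and 30 principal components were computed. Cells were joined to 20 nearest neighbours by shared neighbours and clustered with leidenalg 0.10.2 at resolution 1, giving 31 clusters. The fixed-list genes, mitochondrial, ribosomal, haemoglobin and sex-linked genes were kept out of the clustering. List genes can still follow the clusters through genes that vary with them, as in the cycling cluster.

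Clusters were named from fixed markers of 15 cell classes, by the mean log2 level of the markers over the median cluster (20 CPM added to both). A name needed at least 3 markers above a log2 difference of 0.5 in at least 10% of cells. It also needed a lead of 0.2 over the next class where that class had 3 such markers too, except between T and NK cells. The macrophage-like cluster of 63 cells was thus named with a score of 0.344 against 0.261 for endothelial cells. A name was withheld where the leading genes went against it. Names end in "-like" since they rest on transcripts alone. Markers of eosinophils, mural cells, cardiomyocytes, erythroid cells and platelets named no cluster. The clustering settings, the centring within libraries, the doublet share and this naming rule were set after the files had been opened. An earlier rule, which compared each cluster with the mean of the others, named 9602 cells macrophage-like and left 7698 unnamed. It was replaced while F7 levels per cluster and tag were on view, and its results are among the alternatives.

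F7 was given per class and tag as CPM (all molecules of the class in the tag as the total, at least 20 cells) and as the share of cells with a molecule, with exact Clopper-Pearson 95% intervals. Where a count was 0, the limit given is 3 counts over the total, and only the test of thinned clusters used the upper bound of the interval instead. Intervals and limits cover counting error only. Shares were computed again after every cell was thinned to 1000 molecules with a fixed seed. Cells per tag ranged from 708 to 2494 and median molecules per cell from 11399.5 to 20282.

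Molecule counts were summed per tag and class, at least 20 cells each, and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with TMM factors, filterByExpr and the tag as a block. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Macrophage-like cells were compared with neutrophil-like (16 tags, 10325 genes), monocyte-like (15 tags, 10974 genes) and T/NK-like cells (18 tags, 10820 genes). Only genes of 14 fixed lists (306 genes, 305 of them in the files) were reported, since other genes define the clusters. The lists cover coagulation and fibrinolysis, protease-activated receptors and their signalling ("receptor signalling"), the TGF-beta pathway, integrins, the NADPH oxidase, matrix, cytokines and chemokines, and the interferon response. The others are scavenger receptors, iron and haem, glycolysis and hypoxia, fatty acid oxidation, immediate early genes, and the cell cycle. The SE of a log2 difference is its size over the square root of F, an approximation.

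F7-positive macrophage-like cells (at least 1 F7 molecule) were matched with equally many F7-negative cells of the same tag, cluster and quartile of total molecules, drawn with a fixed seed. Tags with at least 10 cells per set entered (17 tags, 19 to 433 cells per set), and F7 itself was left out of the 9605 genes tested. Tag 5 of library 2 was left out, with 5 positive of 471 macrophage-like cells. The median total of positive over negative cells was 1.03 (0.946 to 1.14 over tags). Lists were also tested with camera (limma 3.58.1) on edgeR's z-scores, with a correlation of 0.01 and with an estimated one. Camera had been run on voom values before, where the estimated correlation differed between repeated runs, the cause of which was not tested. It was replaced after those results had been seen, and with the preset correlation they had also called cytokines, iron and haem, immediate early and cell cycle genes.

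The lists, markers, edgeR comparisons and the rule for named genes were fixed before the data were examined. For each pair of classes the rule named F7, F3, F10, F2rl1, Tgfb1 and Cybb, and from each list the 2 genes with the largest absolute log2 difference past the threshold, at 10 CPM or more in the higher class and in the same direction in at least 90% of tags. For F7-positive cells it named the 10 genes with the smallest adjusted p in each direction, at the same level and in the same direction in at least 75% of tags, with F3, F10, F2rl1, Tgfb1 and Cybb. The text gives part of the named genes in full and the rest as ranges.

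The fits were tested on simulated counts with 200 changed genes, drawn from the real means, totals and dispersions. Of genes changed by log2 1 and 2, 82 and 91% were recovered for neutrophil-like (10325 genes), 92 and 96% for monocyte-like (10974 genes) and 92 and 96% for T/NK-like cells (10820 genes). For F7-positive cells (9605 genes) 62% were recovered at log2 0.25 and 94% at 0.5. The fits called 9, 12, 8 and 12 unchanged genes.

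Alternatives planned were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, no block, each library left out, 50 cells (20 for F7 sets) as the minimum, doublets kept, resolutions 0.5 and 1.5, 500 genes per cell, each library by itself for levels and shares, thinning, and F7 sets not matched on cluster, not matched on total molecules or drawn again. Chosen after the data were seen were each library alone in the tests, cells above 15% mitochondrial molecules left out, the earlier naming rule, the mixed neutrophil-like cluster left out, the T/NK-like cluster rich in macrophage genes left out, matching to the nearest total, and each library left out for the F7 level of classes and clusters, the share of cells with F7 and the macrophage-like share. Other tools were igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15.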

Results

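Leukocytes were isolated from infarcted mouse hearts by CD45 selection after permanent ligation, both from F7fl/fl mice with CX3CR1Cre and from F7fl/fl WT mice, at several time points, and single-cell transcriptomes were read on the BD Rhapsody platform. The subject of the series was coagulation factor VII (F7) made by macrophages and its part in remodelling of the infarcted heart. The 3 samples were 3 multiplexed libraries, replicates 1 to 3 of 1 group, which pooled 7, 5 and 6 hearts told apart by sample tags. They held 15274, 4953 and 5535 cells with 349827525, 88942652 and 93812439 molecules (deduplicated counts), and between 10152522 and 62344127 molecules per tag. The labels and file headers used here assign no genotype or time point to single tags. The run name of library 1 includes d3, which may stand for a day of the whole pool and was not used as one, so values that rest on library 1 may be those of 1 day. Genotypes and times were therefore not compared, and each comparison was made between cells of the same tag.

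F7 is the gene that the floxed allele targets, and its level in macrophage-like cells differed widely between tags. The gene (ENSMUSG00000031443) lies on chromosome 8 at 13026034 to 13035809 of GRCm38, on the plus strand. In CPM, the count scaled to all molecules of these cells, tags 6 to 12 of library 1 held 12.1, 13.1, 9.65, 41.0, 51.3, 22.4 and 44.7. Tags 1 to 5 of library 2 held 53.0, 30.4, 5.77, 6.08 and 1.12. For tags 7 to 12 of library 3 the values were 42.6, 20.8, 4.66, 5.48, 14.8 and 19.2. Which part of F7 the allele removes is not given in the sources used here, so the counts check no genotype, and no tag was assigned to one.

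Macrophage-like cells made up 14804 of the 25128 cells kept, 58.9%, and a median of 61.5% of the cells of a tag (range 48.1 to 68.8, 18 tags). T/NK-like cells (1479) had a median share of 6.80% (1.47 to 14.4), dendritic cell-like cells (1765) 6.41% (4.04 to 9.82) and monocyte-like cells (2518) 4.39% (1.03 to 18.3). Fibroblast-like cells (643) stood at 3.81% (0.667 to 8.82), neutrophil-like cells (969) at 3.07% (0.850 to 11.9) and B cell-like cells (584) at 3.07% (0.614 to 6.09). Endothelial cell-like and mast cell or basophil-like cells were few, 68 and 51, and 2247 cells in 4 clusters were left unnamed. Shares differed between libraries: the median tag held 13.9, 3.65 and 2.95% monocyte-like cells, 2.73, 10.3 and 10.7% T/NK-like cells, 0.971, 4.78 and 4.31% fibroblast-like cells and 1.23, 3.45 and 4.02% B cell-like cells in libraries 1, 2 and 3. The macrophage-like median was 55.5% in library 1 (51.3 to 64.2), 63.8% in library 2 (61.9 to 68.8) and 61.5% in library 3 (48.1 to 67.0).

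F7 transcripts were most abundant in macrophage-like cells, with a median of 17 CPM over 18 tags (range 1.12 to 53.0). Monocyte-like cells held 6.39 CPM (0 to 16.4, 15 tags), neutrophil-like cells 6.91 CPM (0 to 33.1, 16 tags), T/NK-like cells 2.07 CPM (0 to 17.3, 18 tags) and B cell-like cells 1.35 CPM (0 to 49.3, 15 tags). Dendritic cell-like cells held 0.632 CPM (0 to 8.99, 18 tags) and fibroblast-like cells 0 (0 to 4.29, 15 tags). Tags have no genotype here, and mice with CX3CR1Cre were among those pooled. These levels, and the F7 differences between classes below, may thus mix hearts with and without deletion of F7 in cells with Cx3cr1. Taking the tag as a block does not remove this where deletion differs between classes. An F7 molecule was found in 2788 of 14804 macrophage-like cells, 18.8% (95% Clopper-Pearson interval 18.2 to 19.5), at a median of 21011.5 molecules per cell. This pooled share leaned on library 1, with 24.2, 11.8 and 11.3% in libraries 1, 2 and 3 and 11.6% without library 1, and over tags it ran from 1.06 to 38.6% (median 14.8%). The share was 6.0% of monocyte-like cells (5.10 to 7.00, 11684.5 molecules per cell), 5.57% of neutrophil-like cells (4.21 to 7.21, 4536 molecules, 1.59% without library 1) and 2.37% of T/NK-like cells (1.65 to 3.28, 10814 molecules). The background, read from lymphoid cells, which are no known source of coagulation factors, was uneven. The NK cell cluster held F7 in 0 of 273 cells at a median of 7093 molecules, which allows up to 1.1% of cells with a molecule, the larger T cell clusters in 1.29% (8029.5 molecules) and 4.04% (16542 molecules), and B cell-like cells in 4.11% (9822.5 molecules, 2.03% without library 1). The T cell cluster with 4.04% carried macrophage genes at a median of 61.2% of their macrophage level, against 12.7% in the other and 4.06% in the NK cell cluster.

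Depth was evened out by thinning every cell to 1000 molecules, which left F7 in 1.88% of macrophage-like, 0.929% of neutrophil-like, 0.516% of monocyte-like and 0.0567% of dendritic cell-like cells, and in 0 of 1478 T/NK-like cells (a count of 0 allows up to 0.203%). Within libraries 1, 2 and 3, pooled macrophage-like cells held 29.4, 17.7 and 17.5 CPM of F7, monocyte-like cells 6.84, 5.24 and 6.52 CPM, and T/NK-like cells 5.33, 1.28 and 1.98 CPM. The level in neutrophil-like cells rested on library 1, with 22.6 CPM against 2.71 and 5.05 CPM in libraries 2 and 3. Of their 140 F7 molecules, 103 lay in a cluster of 78 cells, 70 of them from library 1, with F7 in 42.3% of cells. This cluster had the highest median doublet score (0.149). The other neutrophil-like cluster, of 891 cells, held 6.40 CPM, with F7 in 2.36% of cells. Without library 1 the median tag held 0, where a count of 0 allows up to 13.6 to 33.6 CPM. Without library 1 the median fell to 0 also in dendritic cell-like and B cell-like cells and to 1.29 CPM in T/NK-like cells. Part of the neutrophil-like, T/NK-like and B cell-like cells also carried transcripts of macrophages such as C1qa, at a median of 30.7, 42.4 and 58.1% of their macrophage level over 14 macrophage genes.

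**Figure D1:**
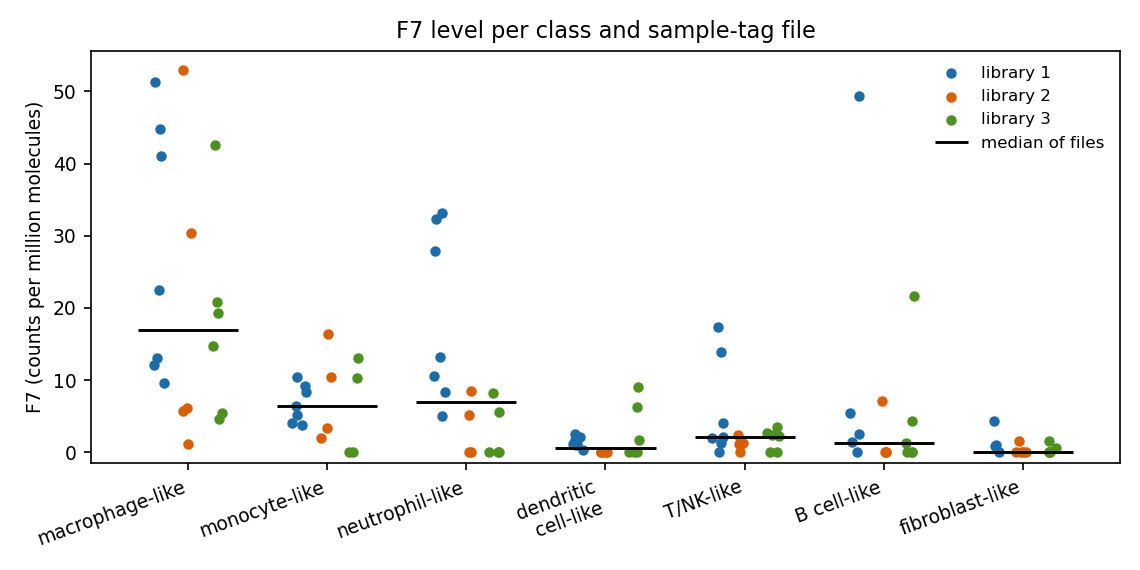
F7 level in CPM (vertical axis) in each cell class (horizontal axis), each point 1 sample tag with at least 20 cells of the class, coloured by library, each bar the median over tags. Macrophage-like cells had the highest median, 17, against 6.91 in neutrophil-like and 6.39 in monocyte-like cells.

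Macrophage-like cells fell into 9 clusters whose F7 levels lay far apart. The cluster marked by Saa3, an acute-phase apolipoprotein, Slpi, a protease inhibitor, and Arg1, the arginase of wound macrophages, held a median of 44.6 CPM of F7 (0 to 86.4, 18 tags). The cluster marked by Gpnmb, a lysosomal glycoprotein, and Fabp4, a fatty acid carrier, held 21.5 CPM (1.97 to 91.8, 16 tags). Lower levels were found in the Ppbp and Arg1 cluster (11.1 CPM, 2.17 to 48.3, 14 tags) and in cycling cells marked by Pclaf and Cenpe (9.22 CPM, 1.53 to 48.1, 12 tags). The Fcrls cluster held 2.71 CPM (0.853 to 22.4, 18 tags). The cluster of antigen-presenting macrophages, with the MHC class II genes H2-Aa and H2-Eb1 and with Cx3cr1, the fractalkine receptor, held 1.93 CPM (0 to 6.02, 18 tags). A cluster led by Lyve1, Cbr2 and Folr2 held 1.19 CPM (0 to 3.76, 10 tags), but these genes were also raised in the Saa3 and Arg1 cluster, so they do not set cells with little F7 apart. Several of these medians leaned on 1 library: without library 1 the Saa3 and Arg1 cluster stood at 23.5 CPM, the Gpnmb and Fabp4 cluster at 13.5 CPM (32.8 without library 2) and the Lyve1, Cbr2 and Folr2 cluster at 0. The other 2 clusters, of 82 and 63 cells and with Saa3 among their leading genes, reached 20 cells in no tag and held 46.8 and 43.5 CPM when pooled, from uneven libraries (73 of the 82 cells from libraries 2 and 3, 56 of the 63 from library 1). The Gpnmb and Fabp4 cluster held 48.2 CPM when pooled.

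In the Saa3 and Arg1 cluster 754 of 1997 cells, 37.8%, had an F7 molecule, against 49 of 2191, 2.24%, in the MHC class II cluster. After thinning to 1000 molecules these were 90 cells, 4.51%, and 3 cells, 0.137%. The pooled levels of the Saa3 and Arg1 cluster and the MHC class II cluster were 50.2 and 2.87 CPM in library 1, 55.1 and 1.70 CPM in library 2, and 44.6 and 1.69 CPM in library 3. The Gpnmb and Fabp4 cluster varied more between libraries, with pooled levels of 55.9, 10 and 26.2 CPM. Clusters were not compared by edgeR, since the genes that define them were found on the same cells.

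**Figure D2:**
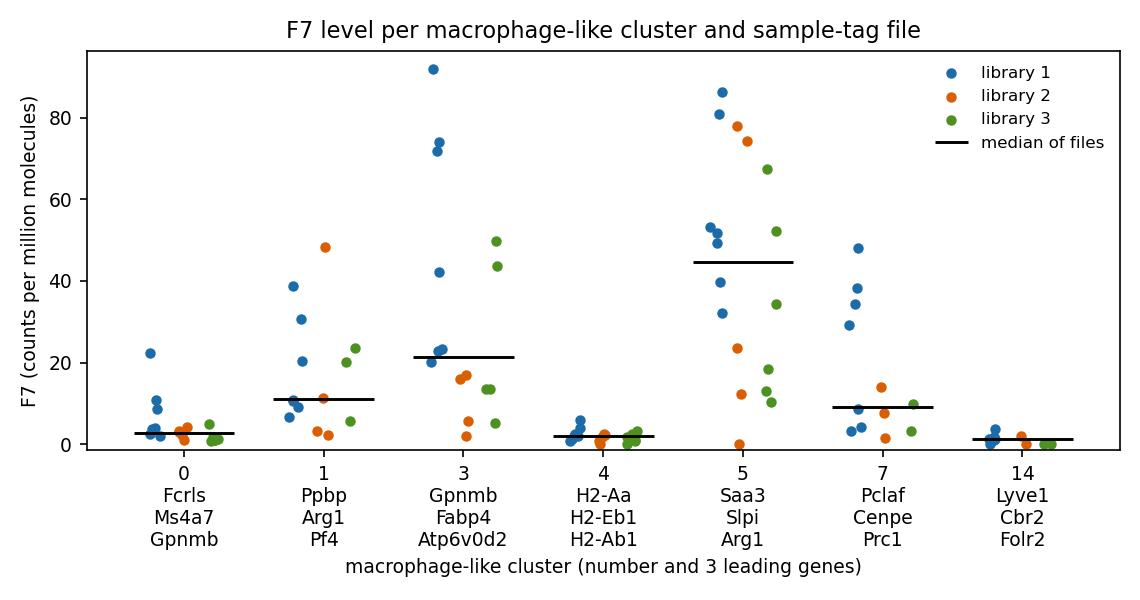
F7 level in CPM (vertical axis) in the macrophage-like clusters (horizontal axis), each point 1 sample tag with at least 20 cells of the cluster, coloured by library, each bar the median over tags. The medians run from 44.6 in the Saa3, Slpi and Arg1 cluster (23.5 without library 1) to 1.19 in the cluster led by Lyve1, Cbr2 and Folr2 (0 without library 1).

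Macrophage-like and monocyte-like cells of the same tag were compared to see how the coagulation genes differ between these classes (15 tags). The classes rest on transcripts, and the origin of the cells was not measured. F7 was 3.52-fold higher in macrophage-like cells (log2 1.82 ± 0.15, SE, edgeR adjusted p 1.03e-10, higher in 14 of 15 tags), with log2 differences of 1.85, 1.59 and 1.67 in libraries 1, 2 and 3. F3, which encodes tissue factor, the receptor of the F7 protein, was 12.7-fold higher (3.67 ± 0.30, edgeR adjusted p 9.35e-11, 15 of 15 tags). F10, whose product the complex of both activates, went the other way and was 5.06-fold lower (-2.34 ± 0.17, edgeR adjusted p 1.29e-11, lower in 15 of 15 tags). F10 (ENSMUSG00000031444) starts 1498 bases downstream of F7 on the same strand, at 13037308 to 13056676. Tgfb1, the profibrotic growth factor, was lower (-1.28 ± 0.061, edgeR adjusted p 6.18e-15, 15 of 15 tags). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was lower by -0.32 ± 0.11 (edgeR adjusted p 0.0102, 9 of 15 tags), a call that rested on library 1: without it the difference was 0.08 (edgeR adjusted p 0.528). F2rl1, which encodes the protease-activated receptor that F7 with tissue factor cleaves, was too low to test, with 17 molecules in macrophage-like and 0 in monocyte-like cells.

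Among genes of the fixed lists, Marco, a scavenger receptor (7.46 ± 0.22), Ccl8, a chemokine (5.51 ± 0.13), and Serpinb6a, an intracellular protease inhibitor (4.65 ± 0.15), were higher in macrophage-like cells in 15 of 15 tags (edgeR adjusted p 1.53e-18, 4.44e-20 and 7.03e-18). Thbs1, an activator of latent TGF-beta (-1.94 ± 0.10), Itgal, the alpha chain of a leukocyte integrin (-3.72 ± 0.24), and Hif1a, the hypoxia regulator (-1.39 ± 0.077), were lower in 15 of 15 tags (edgeR adjusted p 3.21e-14, 1.31e-12 and 9.31e-14). Without library 1 the log2 differences of Ccl8, Serpinb6a and Itgal were 4.63, 3.98 and -2.64. Hbegf, a ligand of the EGF receptor (1.59 ± 0.22, edgeR adjusted p 8.81e-07, 14 of 15 tags), also rested on library 1 and was at 0.45 (edgeR adjusted p 0.147) without it.

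Of 275 list genes tested, 135 were higher and 86 lower in macrophage-like than in monocyte-like cells by edgeR, and 136 and 86 adjusted over the list alone, the genes of all 14 lists together. In the coagulation list 13 of 23 genes were higher and 7 lower, and in the TGF-beta list 6 of 20 were higher and 11 lower, Thbs1 among them. Interferon response genes were higher for 2 and lower for 18 of 25, and NADPH oxidase genes for 2 and 5 of 7. The interferon counts leave out a cluster of 1306 cells with interferon genes among its leading genes. It scored highest on macrophage markers but stayed unnamed, since monocyte markers were among its leading genes. Macrophages rich in these transcripts may therefore be missing from the macrophage-like class. Higher genes prevailed among scavenger receptors (12 higher and 3 lower of 17), iron and haem genes (14 and 2 of 17), fatty acid genes (14 and 2 of 20) and cytokines (20 and 8 of 36). For glycolysis and hypoxia the counts were 5 and 12 of 24, for matrix genes 12 and 8 of 28, for integrins 5 and 5 of 13, for receptor signalling genes 4 and 1 of 7, and for immediate early genes 8 and 4 of 20. All 18 cell cycle genes were higher, and 1274 of the macrophage-like cells formed the cycling cluster.

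**Figure D3:**
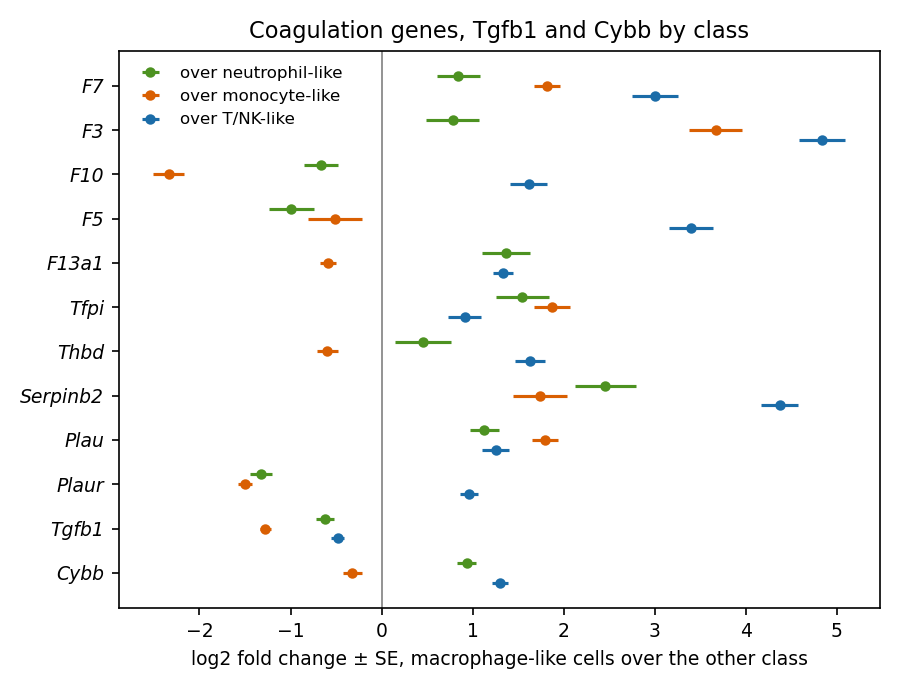
Log2 difference of Tgfb1, Cybb and some genes of the coagulation list (vertical axis) in macrophage-like cells over neutrophil-like, monocyte-like and T/NK-like cells of the same tag (horizontal axis, 3 colours), points showing edgeR estimates and bars 1 SE. F7 lies above 0 in all 3 comparisons (0.84, 1.82 and 3.0), and F10 lies below 0 against neutrophil-like and monocyte-like cells (-0.66 and -2.34) and above it against T/NK-like cells (1.62). Against neutrophil-like cells both calls were lost without the tag as a block, and F10 lay above 0 in library 3.

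Macrophage-like cells were compared with neutrophil-like cells of the same tag, the other phagocytes of the early infarct (16 tags). F7 was 1.79-fold higher in macrophage-like cells (0.84 ± 0.24, edgeR adjusted p 0.00382, 15 of 16 tags), but library 1 alone did not pass (0.44, edgeR adjusted p 0.0703), and without library 1 the difference was 2.47. The last value includes tags with 0 F7 molecules in neutrophil-like cells. Their limits, 13.6 to 33.6 CPM, lay above the macrophage-like level of the same tag except in tag 8 of library 3. F3 was higher by 0.78 ± 0.29 (edgeR adjusted p 0.0242, 10 of 16 tags), a call lost without library 3 (0.58, edgeR adjusted p 0.140). Without library 1 the difference of F3 was 1.36 (edgeR adjusted p 0.0105). F10 was lower by -0.66 ± 0.19 (edgeR adjusted p 0.00447, lower in 12 of 16 tags), a call lost without library 1 (-0.17, edgeR adjusted p 0.510), and lay at 0.16 in library 3. Without the tag as a block the calls of F7, F3 and F10 were all lost (0.61, 0.88 and -0.54, edgeR adjusted p 0.237, 0.0985 and 0.0803). Tgfb1 was lower (-0.62 ± 0.096, edgeR adjusted p 4.67e-06) and Cybb higher (0.93 ± 0.11, edgeR adjusted p 4.03e-08), each in 16 of 16 tags. F2rl1 was not tested, with 2 molecules in neutrophil-like cells. A neutrophil-like cluster of 78 cells also carried Gpnmb and Fabp4 of macrophages, and without it, an alternative chosen after the clusters were seen, F7 differed by 1.92 and F3 was no longer called (0.51, edgeR adjusted p 0.144).

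Csf1, the growth factor of macrophages, was 110-fold lower in macrophage-like cells (-6.77 ± 0.20, edgeR adjusted p 2.42e-20, 16 of 16 tags). Mmp9, a gelatinase (-5.38 ± 0.39, edgeR adjusted p 6.25e-12, -6.38 without library 1), and Itgal (-4.00 ± 0.15, edgeR adjusted p 4.70e-18) were lower in 16 of 16 tags. Il6, an inflammatory cytokine (3.60 ± 0.26, edgeR adjusted p 5.90e-12, 16 of 16 tags), and Marco (5.87 ± 0.36, edgeR adjusted p 1.44e-13, 15 of 16 tags) were higher. By edgeR 126 of 269 list genes were higher and 84 lower in macrophage-like cells, and 128 and 88 adjusted over the list alone. The median log2 difference of all genes tested was 0.12 with TMM factors and 0.28 with DESeq2 size factors, a shift of 0.16, with which 141 list genes were higher and 69 lower, and none of the 32 genes named by the fixed rule changed direction.

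Interferon response genes were lower in macrophage-like than in neutrophil-like cells for 21 and higher for 1 of 25 (18 and 1 with DESeq2 size factors), again with the unnamed cluster of interferon genes left out. Of the coagulation list 11 of 22 genes were higher and 5 lower with either scaling, and of the TGF-beta list 4 of 21 were higher and 9 lower (6 and 7 with DESeq2 size factors). NADPH oxidase genes gave 2 higher and 4 lower of 7, glycolysis and hypoxia genes 10 and 9 of 24 (11 and 6 with DESeq2 size factors), and receptor signalling genes 2 and 1 of 7. Scavenger receptors (12 and 2 of 17), iron and haem genes (10 and 3 of 17), fatty acid genes (13 and 2 of 20), matrix genes (14 and 6 of 25) and cytokines (17 and 9 of 34) were more often higher than lower. Integrins split 5 and 5 of 12, immediate early genes 7 and 8 of 20 (8 and 7 with DESeq2 size factors), and all 18 cell cycle genes were higher.

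Against T/NK-like cells of the same tag (18 tags), the lymphoid reference, F7 was 8.03-fold higher in macrophage-like cells (3.0 ± 0.25, edgeR adjusted p 9.73e-11, 18 of 18 tags), and by 3.63 without library 1. F3 was 28.7-fold higher (4.84 ± 0.25, edgeR adjusted p 1.03e-14) and F10 3.06-fold higher (1.62 ± 0.21, edgeR adjusted p 1.50e-07, 2.35 without library 1), both in 18 of 18 tags. F2rl1 was lower in macrophage-like cells by -7.98 ± 0.32 (edgeR adjusted p 3.84e-17, 18 of 18 tags, -6.75 without library 1), from 17 molecules against 285 in T/NK-like cells. F2r, the thrombin receptor gene, was 88.6-fold lower (-6.47 ± 0.23, edgeR adjusted p 6.90e-18, 18 of 18 tags, -5.76 without library 1). Tgfb1 was lower (-0.48 ± 0.071, edgeR adjusted p 1.55e-06) and Cybb higher (1.30 ± 0.089, edgeR adjusted p 2.13e-12), both in 18 of 18 tags.

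Serpinb2, an intracellular serpin (4.37 ± 0.20, edgeR adjusted p 1.18e-15), and Fn1, the matrix protein fibronectin (2.65 ± 0.15, edgeR adjusted p 3.76e-14), were higher in macrophage-like than in T/NK-like cells in 18 of 18 tags. Smad7, an inhibitor of TGF-beta signalling, was lower (-2.10 ± 0.065, edgeR adjusted p 2.96e-19, 18 of 18 tags). Of 275 list genes 188 were higher and 50 lower by edgeR, and 189 and 50 adjusted over the list alone. In the coagulation list 21 of 22 genes were higher, the exception being Fgl2, chosen after the values were seen (-0.34). Scavenger receptors were higher for 18 of 18, cytokines for 29 of 34 with 2 lower, matrix genes for 19 of 27 with 1 lower, iron and haem genes for 15 of 16 with 1 lower, and glycolysis and hypoxia genes for 19 of 24 with 3 lower. Fatty acid genes gave 15 higher and 2 lower of 20, NADPH oxidase genes 6 and 1 of 7, integrins 8 and 5 of 13, and receptor signalling genes 5 and 4 of 9. The TGF-beta list gave 9 and 7 of 22, immediate early genes 12 and 7 of 20, and cell cycle genes 6 and 3 of 18. Interferon response genes gave 6 and 13 of 25, again with the unnamed cluster of interferon genes left out. Since 1 T/NK-like cluster of 693 cells carried macrophage genes, it was left out in an alternative chosen after the clusters were seen, which gave 185 higher and 54 lower and an F7 difference of 4.23.

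Macrophage-like cells with an F7 molecule were compared with cells without one, of the same tag, cluster and quartile of total molecules (17 tags, 2402 cells in each set), to see which genes accompany F7 within clusters. Cd300lf, an inhibitory lipid receptor (0.59 ± 0.047, edgeR adjusted p 3.09e-08), Fabp5, a fatty acid carrier (0.65 ± 0.058, edgeR adjusted p 1.21e-07), and Gpnmb (0.71 ± 0.077, edgeR adjusted p 9.59e-07) were higher in F7-positive cells in 17 of 17 tags. Plpp3, a lipid phosphatase, was 2.27-fold higher (1.18 ± 0.13, edgeR adjusted p 1.08e-06, 15 of 17 tags), with 1.48, 0.63 and 0.67 in libraries 1, 2 and 3 and 0.66 (edgeR adjusted p 0.0454) without library 1. Fcrls, a gene of long-resident macrophages (-0.97 ± 0.085, edgeR adjusted p 1.15e-07), Cx3cr1 (-1.09 ± 0.11, edgeR adjusted p 2.21e-07) and Csf1r, the receptor of Csf1 (-0.29 ± 0.029, edgeR adjusted p 2.21e-07), were lower in 17 of 17 tags. Several of these genes mark the clusters themselves. Gpnmb leads a cluster with much F7, but is also among the leading genes of the Fcrls cluster with little. Fcrls is also among those of the Ppbp and Arg1 cluster, and Cx3cr1 among those of the MHC class II cluster. The differences were therefore not shown to lie apart from macrophage subtype. F10 was 1.59-fold higher (0.66 ± 0.099, edgeR adjusted p 5.44e-05, 15 of 17 tags), and reads were not tested for spill between the neighbouring F7 and F10 genes. F3 (0.21 ± 0.11, edgeR adjusted p 0.276, 9 of 17 tags), Tgfb1 (0.01 ± 0.045, edgeR adjusted p 0.982, 11 of 17) and Cybb (0.07 ± 0.042, edgeR adjusted p 0.352, 12 of 17) were not called, and F2rl1 was too low to test. F3 was called, however, with no filter, with doublets kept and without matching on cluster.

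Of 9605 genes, 599 were higher and 481 lower in F7-positive cells by edgeR. Without library 1 these were 164 and 181, with library 2 alone 64 and 58, and with library 3 alone 22 and 43. The count depended on pairing by tag: without the tag as a block edgeR called 0 genes, with 642 at an unadjusted p under 0.05, while DESeq2 with the block called 643 and 555. The other genes named by the fixed rule were Msrb1, Prdx6, Lgals3, Gngt2, Gpc1 and Gsr, higher by 0.33 to 0.79, and Eid1, Ctsc, Cd72, Tmem176b, Slamf9, Col14a1 and Psd3, lower by -0.33 to -1.19. Of the 24 tested genes named by that rule, 23 had the same sign within each of the 3 libraries, Tgfb1 being the exception. F7-positive cells had at least 1 molecule, and F7-negative cells were those in which none was detected.

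Glycolysis and hypoxia genes were higher in F7-positive cells for 17 of 23 genes and lower for none (0.17 to 0.63), led by Egln3, an oxygen sensor (0.63 ± 0.083, edgeR adjusted p 1.29e-05). With DESeq2 size factors 16 of them were called. Sets made in the same way from 20 other genes, given below, were counted for all calls but not by list. Whether detecting a molecule of any gene gives such a shift of a list was therefore not tested. Of the matrix list 10 of 23 genes were higher and 2 lower, Mmp12, the macrophage elastase (0.79 ± 0.12, edgeR adjusted p 5.44e-05), and Spp1, osteopontin (0.67 ± 0.10, edgeR adjusted p 7.89e-05), among the higher. In the coagulation list 4 of 19 were higher and none lower: F10, F5, the cofactor of F10 (0.64 ± 0.12, edgeR adjusted p 0.000592), Serpinb2 (1.01 ± 0.22, edgeR adjusted p 0.00336) and Anxa2, a plasminogen receptor (0.16). Of the TGF-beta list 1 gene was higher, Thbs1 (0.42), and 4 of 19 lower, both receptor genes Tgfbr1 (-0.21) and Tgfbr2 (-0.25) among them. The scavenger receptor Cd163 was lower (-0.88 ± 0.25, edgeR adjusted p 0.0197). These list members, apart from F10, were chosen after the values were seen.

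For cytokines 8 of 35 genes were higher and 4 lower in F7-positive cells, for iron and haem genes 5 and 2 of 16, for scavenger receptors 3 and 2 of 18, for integrins 3 and 2 of 12, and for fatty acid genes 2 and 0 of 20. Receptor signalling genes gave 0 higher and 2 lower of 7 (Arrb2 and Gna12, chosen after the values were seen), cell cycle genes 0 and 4 of 18, immediate early genes 1 and 3 of 20, and NADPH oxidase genes 1 and 0 of 7. Of 25 interferon response genes 1 was higher, Isg20, chosen after the values were seen, and its call was lost with DESeq2 size factors. Over all 14 lists 56 of 262 genes were higher and 25 lower by edgeR, and 65 and 31 adjusted over the list alone.

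By camera on edgeR's z-scores with a preset correlation of 0.01, glycolysis and hypoxia genes ranked higher than other genes (adjusted p 8.40e-17, and 0.0152 with an estimated correlation), as did matrix genes (4.80e-05 and 0.0170) and fatty acid genes (0.00847 and 0.0170). TGF-beta genes ranked lower (adjusted p 0.0130 and 0.0253 by camera). The calls of the coagulation list, higher at a camera adjusted p of 0.0190, and of receptor signalling genes, lower at 0.0120, were lost with an estimated correlation (adjusted p 0.0719 and 0.0576). Cytokines (camera adjusted p 0.276), iron and haem (0.0980), immediate early (0.0980), cell cycle (0.595), NADPH oxidase (0.215), interferon response (0.525), scavenger receptor (0.276) and integrin genes (0.996) were not called with the preset correlation. The scavenger receptor list had a median of 0.04, a mean of -0.01 and an upward test, and the integrin list a median and mean of 0.01 and a downward test.

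**Figure D4:**
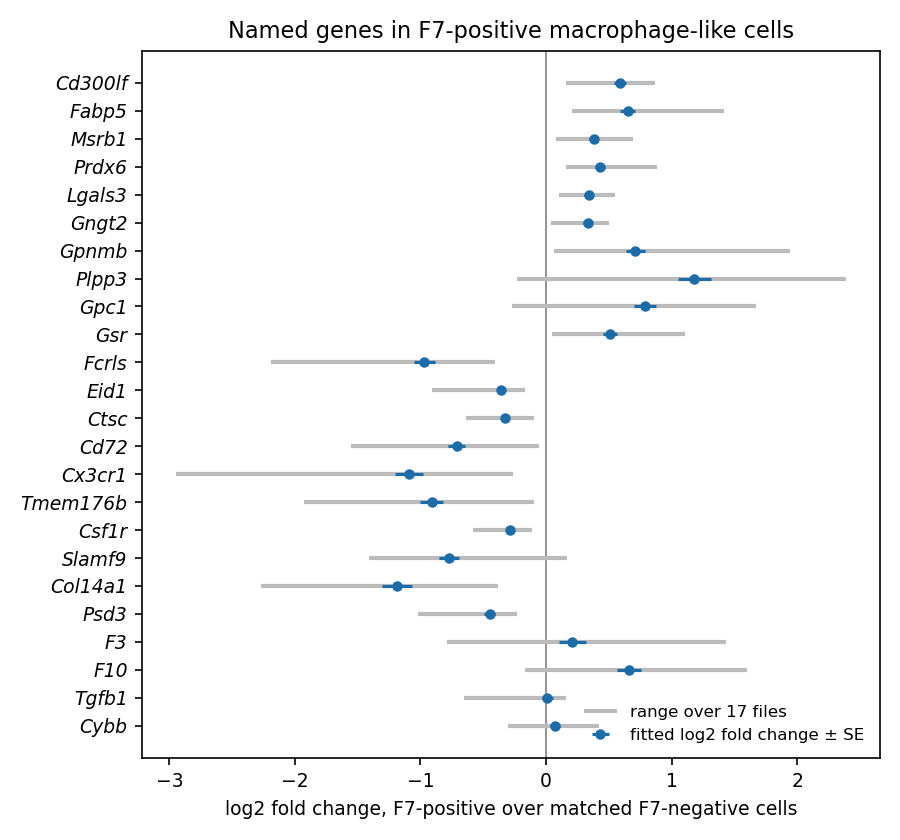
Log2 difference between F7-positive and matched F7-negative macrophage-like cells (horizontal axis) of the genes named by the fixed rule (vertical axis), points showing edgeR estimates with bars of 1 SE, grey bars the range over 17 sample tags. Plpp3 lies highest at 1.18 (0.66 without library 1) and Col14a1 lowest at -1.19, and F3, Tgfb1 and Cybb lie at 0.21, 0.01 and 0.07.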

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

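The tests with cells matched to the nearest total and on single neutrophil-like clusters were chosen after the results were seen. B cell-like cells made up 5.80% of the cells of tag 12 of library 3, above the other 5 tags of that library (3.35 to 4.23%). The gap to the nearest tag was 0.642 of the range, against a critical value of 0.625 for 6 tags. Over the 30 groups of tags tested, chance alone marks about 1 in 20, so a single such tag is no more than chance gives.

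Unnamed clusters entered no comparison and held F7 above the limit of a count of 0. The cluster of monocyte and interferon genes Ms4a4c, Slfn4 and Ly6c2 (1306 cells), which scored highest on macrophage markers, held 11.4 CPM, with F7 in 135 cells. A cluster of 708 cells with few molecules (median 2386.5 per cell), 695 of them from library 1, held 18 CPM. A cluster marked by Saa3 (118 cells, 114 of them from library 1, 17.3% mitochondrial molecules) held 74.9 CPM. The osteoclast-type cluster of Atp6v0d2, Acp5 and Nfatc1 (115 cells, 103 from library 1) held 1.19 CPM.

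F7 levels differed between macrophage-like clusters, high when pooled in the Gpnmb and Fabp4 cluster and in 3 with Saa3, 2 of them small and from uneven libraries, and low in the MHC class II cluster and the one led by Lyve1, Cbr2 and Folr2, genes also raised in the Saa3 and Arg1 cluster. Depth is argued against, since after thinning the lower bound of the highest share of cells with F7 (7.32%, in a cluster of 82 cells with Saa3 and Pclaf) was 2.75 times the upper bound of the lowest (0%, in the Lyve1, Cbr2 and Folr2 cluster), a bound that replaced a plain ratio once the lowest share had come out at 0. A difference between libraries is argued against by a ratio of Saa3 and Arg1 to MHC class II cells of at least 17.5 within each library, and free RNA by levels at least 2-fold apart, beyond their intervals, in 17 of 18 tags (the exception was tag 5 of library 2). The pooled levels had been seen when these tests were written, and in the last the extreme clusters were picked within each tag. A state-dependent level of F7 may underlie the pattern, but no biological explanation was tested, since the design gives no group for it. Mice with CX3CR1Cre were among those pooled, and tags have no genotype here. Deletion of F7 in cells with Cx3cr1 can therefore not be told apart from such a level.

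Genes differed between F7-positive and matched F7-negative cells. The number called, 1080, was reached by 1 of 60 splits that swap the sets within tags, the real one. The highest other split called 0. A chance labelling of the 2 sets within tags is thus argued against, as far as 60 splits can show. The swaps kept the drawn cells, so they do not test chance in the draw of F7-negative cells. Of 20 other genes detected in as many cells, 1 gave sets calling as many genes, Spn with 1473, itself a monocyte marker. The median was 32, with no call for 6 genes, but Pcp4l1, Stard4 and Rasgrp2 gave 533, 350 and 338. Detection of any gene of that frequency is thus argued against only weakly as the source of the whole count, Spn being the exception, and may give part of it. The match was on cells only, with 3433 to 7333 molecules against 9331 of F7, so no gene with as many molecules was tested. Total molecules left uneven within quartiles are argued against only narrowly. With cells matched to the nearest total 751 calls, 69.5% (66.7 to 72.3), were shared, where 66.67% had been set as the bound. The interval takes genes as independent and is therefore too narrow. Another draw in quartiles shared 786, so calls were also lost by drawing anew. A finer macrophage state within clusters may account for it, and spill of reads between F7 and F10 stays open for F10, and no biological explanation was tested. Nor can deletion of F7 in cells with Cx3cr1, where mice carried CX3CR1Cre, be told apart from such a state.

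F7 molecules were seen in neutrophil-like, T/NK-like and B cell-like cells. Macrophage RNA in or with these cells, measured on 14 fixed macrophage genes with C1qa, C1qb and Apoe among them, predicts more than was seen in T/NK-like cells (observed over expected 0.308, interval 0.234 to 0.398) and in B cell-like cells (0.524, 0.387 to 0.692), so it could account for all of theirs. In neutrophil-like cells the ratio was 1.87 (1.57 to 2.21), but with the largest share any single gene allows, Csf1r at 50.9%, its lower bound was 0.948, so their own F7 and macrophage RNA cannot be told apart. The neutrophil-like cluster without Gpnmb and Fabp4 gave 1.93 (1.36 to 2.66), with a lower bound of 0.351 at its largest share, so it does not settle this. No biological explanation was tested.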

How the results depend on the processing

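The tests on each library alone, without cells rich in mitochondrial molecules, with the earlier naming rule, without the mixed neutrophil-like or the macrophage-rich T/NK-like cluster and with nearest matching were chosen after the results were seen. Over 11 other settings chosen in advance the list genes higher in macrophage-like cells numbered 109 to 145 against neutrophil-like, 109 to 143 against monocyte-like and 177 to 198 against T/NK-like cells, and those lower 63 to 84, 64 to 100 and 38 to 51, each within 1.5 times the reported count. Without the tag as a block the counts higher and lower were 119 and 80, 124 and 74, and 178 and 46. With library 2 alone 40, 53 and 31 were lower against neutrophil-like, monocyte-like and T/NK-like cells, and with library 3 alone 55 and 46 against the former pair, where fewer tags were tested.

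Genes higher and lower in F7-positive cells numbered 0 and 0 by edgeR without the block, with 642 at an unadjusted p under 0.05, against 643 and 555 by DESeq2 with the block. That fit adds the spread between tags to the error. Leaving out each library gave 164 to 537 higher and 181 to 443 lower, the lowest without library 1. Libraries 2 and 3 alone gave 64 and 22 higher and 58 and 43 lower, with fewer tags. Sets not matched on cluster gave 1291 higher and 1190 lower, and sets not matched on total molecules 770 lower, the cause of which was not tested.

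The 118 named gene results had 1988 values under the alternatives, of which 1921 kept direction and side of the threshold, 56 were no longer called, 3 became called and 8 reversed, and 87 results kept both throughout. Reversed were F10 against neutrophil-like cells with library 3 alone (0.16) and Cybb against monocyte-like cells with libraries 2 and 3 alone (0.11 and 0.07) and over the libraries left out (-0.51 to 0.08, highest without library 1). Tgfb1 in F7-positive against F7-negative macrophage-like cells, not called, reversed without the block (-0.0032), with library 2 alone (-0.07), without matching on total molecules (-0.03) and over the libraries left out (-0.03 to 0.02). The cause was not tested. Marco, Mmp25 and Steap4 gave no value under some settings, where the filter left them out. F7 in macrophage-like against neutrophil-like cells lost its call without the block (0.61, edgeR adjusted p 0.237). F3 in F7-positive against F7-negative macrophage-like cells was called with no filter (edgeR adjusted p 0.0483), with doublets kept (0.39, edgeR adjusted p 0.0283) and without matching on cluster (1.70).

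The F7 level in macrophage-like cells was 6.08 CPM in library 2 alone, and 14.8 to 19.2 under the alternatives added, and the thinned share, 1.88%, is on another scale. In the other classes 9 values under settings chosen in advance, the thinned shares among them, and 3 under those added moved. Their share of cells was 55.5% in library 1 alone and 41.8% with the earlier naming rule, which left more cells unnamed. Depth limits the low classes: DC-like, B cell-like and T/NK-like medians of F7 rest on a few molecules per tag. In libraries 2 and 3 so do those of neutrophil-like cells, whose counts of 0 allow up to 13.6 to 33.6 CPM.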

Other observations

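The tests of chance for the neutrophil-like and monocyte-like comparisons were chosen after the results were seen. The genes named here were picked from the fixed coagulation and receptor signalling lists after their values were seen. Fibroblast-like cells, which CD45 selection would remove and of which 249 of 643 formed a cluster with 55.0% mitochondrial molecules, carried several regulators of clotting. Their median levels over 15 tags were 152 CPM of Plat, tissue plasminogen activator (77.9 to 197), and 81.0 CPM of Tfpi, the inhibitor of tissue factor with F7 (60.8 to 109). The thrombin receptor gene F2r stood at 124 CPM (82.5 to 228) and F3 at 15.9 CPM (6.53 to 56.4). Vkorc1 and Ggcx, the vitamin K enzymes that F7 and F10 need to become active, stood at 202 CPM (95.3 to 247) and 49.7 CPM (17 to 78.4).

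Monocyte-like cells held 348 CPM of F10 (174 to 464) and 622 CPM of F13a1, the fibrin cross-linker (242 to 983), against 51.6 and 324 CPM in macrophage-like cells. Procr, the receptor of protein C, stood at 26.7 CPM in dendritic cell-like cells (5.92 to 73.5). T/NK-like cells held 37.4 CPM of F2r (21.6 to 62.8) and 15.4 CPM of F2rl1 (2.36 to 31.4).

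Swapping the classes within random tags was run as a test of chance for the counts of list genes. Against neutrophil-like cells 210 list genes were called, reached by 1 of 60 splits, the real one, and the highest other split called 31. Against monocyte-like cells 221 were called, and against T/NK-like cells 238, each reached by 1 of 60 splits, the real one, with 0 in the highest other. These splits cannot decide whether chance gave the counts, since the classes were found on the same cells and named by the same markers in every tag. List genes were kept out of the clustering but can follow the genes used in it. The real split was thus all but certain to call the most, and the splits do not test the classes themselves.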
